A study of Rattus norvegicus and Heterocephalus glaber with 6 samples.

How the data were processed

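Liver polyadenylated RNA was sequenced from rats and from naked mole rats, a subterranean rodent that tolerates low oxygen, after 8 hours in 8% oxygen, with 3 libraries per species, per the labels. Normoxia libraries, which the series design mentions, were not used here, so no effect of oxygen was tested and the comparison available was between the species under the same exposure. Replicates are separate samples by their labels; nothing in the labels says that each came from a different animal, so the p-values measure the spread between these samples, which may in part be technical.

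The values are FPKM (fragment values scaled by transcript length and by the number of mapped fragments), per the file headers, which have the columns of a Cufflinks gene table with a locus, a status and confidence bounds for each row. The submitters' processing notes name Bowtie2 2.1.0, TopHat2 2.0.9, Cufflinks 2.1.1 and Picard 1.137. The genome builds and annotations behind the tables are not given in the sources used here, so coordinates are printed as the deposited tables give them. FPKM values carry no read counts, so the absolute depth of the libraries is unknown and no counting interval was computed. In the rat libraries, ratios of values under 0.1 FPKM pile up at a common step, from which the depth of rat 1 was 1.05 times that of rat 2 and 0.983 times that of rat 3. The naked mole rat tables held too few such rows (14 or 15 per pair of libraries) for this estimate.

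Each rat table as used here held 22549 rows with 22517 symbols and each naked mole rat file 734 rows with 567 symbols. Of the naked mole rat rows, 56 had no symbol and 127 were named as olfactory receptors. In all, 296 overlapped another row, so their values need not be separate. The median genomic span was 53489.5 bp for naked mole rat rows and 12614 bp for rat rows, and 326 naked mole rat rows were longer than 100 kb, the longest being 3493995 bp. A rat albumin value was available in 1 library, because Alb carries the status HIDATA, which Cufflinks gives to a locus with too many fragments to estimate, and is listed at 0 in rat 1 and rat 2; both were treated as missing. Another 9 rows in each rat library carry the status LOWDATA and were used as deposited. Of the rat rows, 831 lay on sequence outside the assembled chromosomes, and 0 of these were above 0 in any library, against 73.0% of the 21718 other rows. Between 10.3% and 10.9% of the rat values above 0, and between 6.84% and 7.81% of the naked mole rat values, lay outside their own row's confidence bounds, so these bounds were not used.

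Symbols were matched between species without regard to case, and rows with the same symbol were summed, which gave 388 shared symbols. For 374 of these, each species had 1 row. The naked mole rat row spanned 0.5 to 2 times the rat row for 77 symbols (comparable span), more for 223 (long) and less for 74 (short); these limits were set after seeing the data. Libraries were scaled by the median ratio over shared symbols above 0 in all libraries, with factors of 0.820 to 0.913 in naked mole rat and 1.08 to 1.23 in rat. This scale rests on symbols whose rows often differ in extent between the species. Symbols with a scaled FPKM of at least 1 in at least 3 libraries were tested (289 symbols) with limma 3.58.1 in R 4.3.3 on log2(scaled FPKM + 1), with an intensity trend and Benjamini-Hochberg adjustment. A symbol was called at an adjusted p under 0.05 and a log2 difference of at least 1. Fold differences are on the log2(scaled FPKM + 1) scale, which understates the difference of low genes, and none is given against a species listed at 0. Gene lists for liver metabolism, responses to low oxygen and liver cell types were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested, with an estimated correlation and limma's fry as alternatives. The other alternatives were scaling, pseudocount, filter, treatment of multigene families and of symbols with several rows, the thresholds, the intensity trend, a block for replicate number, and leaving out each library.

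The naming rule was also fixed before the data were examined. It takes, per direction, the 12 largest called differences with a mean of at least 10 in the higher species and of at least 1 in the lower, with no overlap between the species' libraries, and 5 more with the lower species under 1. It adds up to 2 called members per list and direction, a set of focus genes whatever their result, and the 10 most abundant rows per species. Genes outside it were chosen after their values were seen and are marked so. Some genes that the rule takes are not reported here. Genes of families such as cytochromes P450 (CYP), UDP-glucuronosyltransferases (UGT), serpins and ribosomal proteins have near-identical copies that can split reads, so their values are uncertain.

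The limma step was tested on 20 simulated sets with a median of 275 tested genes and 60 changed. It recovered 97.2% of genes changed by 1.5 on the log2 scale and 99.5% of those changed by 3, and called 0.0466% of unchanged genes. Apart from the changed genes, the simulated groups had the same mean levels. These sets therefore do not test the scaling between the species or rows of unlike extent, and give no error rate for those. In rat alone, the median SD of a list's members between the 3 libraries, on log2(FPKM + 1), was set against 10000 random lists matched on mean expression, as a description of these libraries with no p-value. Tested on 30 random lists of 20 genes, this step gave a median percentile of 55.0, and on 30 lists with doubled spread 99.9. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.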

Results

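Livers of rats and naked mole rats held at 8% oxygen for 8 hours were profiled by RNA sequencing, with 3 libraries per species. The FPKM values of a rat library summed to between 527133 and 557187 over 22549 rows, of which 9866 to 10036 reached 1 FPKM. The naked mole rat tables used here held 734 rows, with sums of 17543 to 21793 and 304 to 319 rows at 1 FPKM or more. These tables covered few liver genes, and the absolute depth of the libraries is unknown. Across rows with a mean of at least 1 FPKM, the median SD between replicates on log2(FPKM + 1) was 0.137 in rat (9995 rows) and 0.201 in naked mole rat (319 rows). Over the 289 symbols tested between the species, on scaled values, it was 0.110 in rat and 0.153 in naked mole rat. Over 2 libraries at a time it was 0.0914 to 0.145 in naked mole rat, the lowest without naked mole rat 3, and 0.0853 to 0.0964 in rat. Pearson's r between libraries of a species ran from 0.993 to 0.994 in rat and from 0.982 to 0.990 in naked mole rat.

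Several of the most abundant rat transcripts encode secreted plasma proteins. The most abundant row with 3 values was LOC259246, at 24834 ± 6110 FPKM (SD, n = 3) or 4.64% of the FPKM total. Apoe, an apolipoprotein of lipid transport, followed at 16121 ± 2502 (SD, n = 3), then Apoc1 at 13705 ± 2958, haptoglobin (Hp), which binds free haemoglobin, at 12857 ± 4440, transferrin (Tf) at 12540 ± 1294 and transthyretin (Ttr) at 11035 ± 1643. Ambp reached 7750 ± 915, Rup2 6766 ± 451 and Serpina1, an antiprotease with near-identical family members, 6695 ± 1049. Albumin had 1 usable value, 25789 FPKM in rat 3. The 10 highest rows of a library made up 23.0% to 24.5% of its total. Albumin, 4.63% of the total in rat 3, is missing from the totals of rat 1 and rat 2, so shares are not on the same footing across the rats.

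In naked mole rat, members of the CYP and UGT families led the rows that carried a symbol. CYP1A2 stood at 2248 ± 619 FPKM (SD, n = 3), 11.6% of the table's total, CYP27C1 at 1951 ± 337, and 2 rows named CYP2B6 at 1405 ± 261 and 447 ± 226. UGT1A5, a glucuronosyltransferase, followed at 677 ± 194 and CYP3A5 at 514 ± 65.8. GPX1, a glutathione peroxidase that reduces hydrogen peroxide, was at 347 ± 101, ERCC1, a DNA repair gene, at 294 ± 29.6 and PSMC4, a proteasome subunit, at 243 ± 65.3. The row of highest mean, on scaffold130497 from 634 to 1294, carried no symbol and reached 6550 ± 1770 FPKM. Copies of CYP and UGT genes can split reads, and the ERCC1 and PSMC4 rows span 2493884 and 1514351 bp, far more than the rat genes. Shares of the total differ in meaning between the species, since the naked mole rat tables hold fewer rows.

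The genes of oxygen sensing and metabolism in the focus set were measured mainly in rat. Ldha, the lactate dehydrogenase of anaerobic glycolysis, stood at 1567 ± 79.8 FPKM (SD, n = 3), Vegfa, an angiogenic factor, at 91.9 ± 23.5 and Hmox1, haem oxygenase, at 73.5 ± 33.9. Of the sensing machinery itself, Epas1 (the HIF-2 alpha subunit) was at 56.9 ± 6.25, Hif1a at 8.54 ± 1.42, the prolyl hydroxylases Egln1 and Egln3 at 30.8 ± 5.22 and 2.38 ± 1.40, and Vhl at 2.27 ± 0.200. Slc2a1, a glucose transporter, was at 2.28 ± 0.0708, Adm at 2.30 ± 1.02, and erythropoietin (Epo) lay below 1 FPKM in each library, at 0.704, 0.174 and 0.0815. Of 24 antioxidant genes in the rat tables, 7 reached 100 FPKM, with a list median of 37.2. Superoxide dismutase (Sod1) was at 1726 ± 106, catalase (Cat) at 941 ± 152; Txnrd1 stood at 26.4 ± 2.12 and Nfe2l2, the regulator of antioxidant genes, at 16.6 ± 3.38. Gpx1 was listed at 0 in the 3 rats, on a row outside the assembled chromosomes. Igf1 was at 197 ± 18.5, Pck1, of gluconeogenesis, at 802 ± 344, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis in a family with many copies, at 49.4 ± 16.7.

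**Figure D1:**
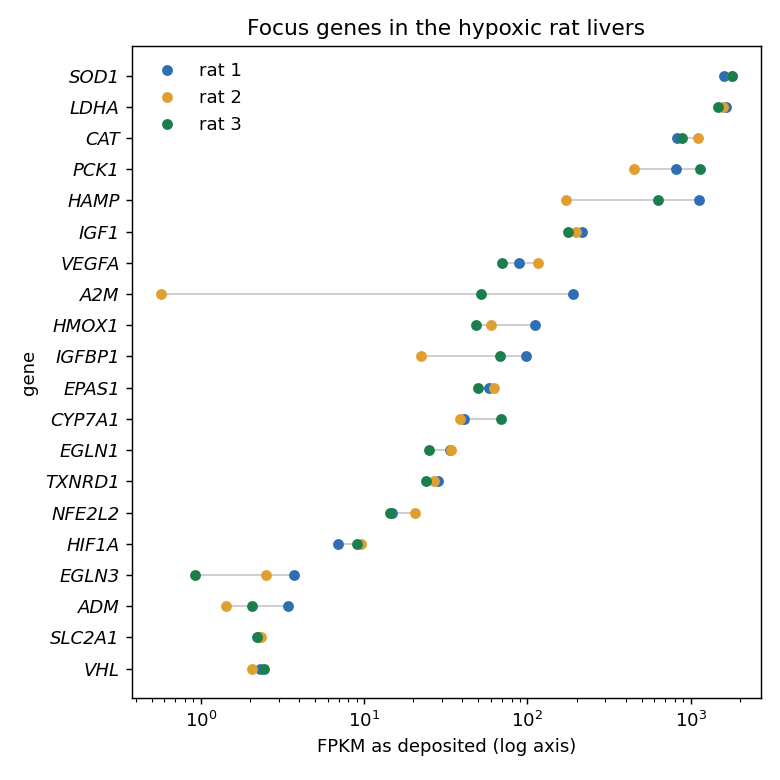
Each row is one of the focus genes reported here with a mean of at least 1 FPKM in rat, each point 1 of the 3 rat libraries, and the x axis is FPKM as deposited on a log axis; grey lines join the lowest and highest library. A2M spans 0.571 to 191 FPKM and HAMP 173 to 1124, while SLC2A1 lies between 2.21 and 2.35.

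A few focus genes differed widely among the rats. A2m, alpha-2-macroglobulin, an acute-phase protein of the rat, was at 191 FPKM in rat 1, 0.571 in rat 2 and 52.3 in rat 3. Hamp, the iron hormone hepcidin, was at 1124, 173 and 627, and Igfbp1, a growth factor binding protein, at 97.5, 22.4 and 68.4.

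Of 38 genes listed as targets of hypoxia-inducible factors, 34 were in the rat tables and 27 reached a mean of 1 FPKM, 16 of them 10 FPKM. Of the hepatocyte markers, 11 of 14 reached 100 FPKM. Among other liver cell types, 10 of 14 macrophage or Kupffer cell markers, 3 of 12 sinusoidal endothelial markers and 4 of 14 stellate or fibroblast markers reached 10 FPKM. Of the T or NK cell markers 3 of 16 reached 1 FPKM, of the neutrophil markers 4 of 14, of the B or plasma cell markers 1 of 8, of the cholangiocyte markers 3 of 9 and of the proliferation markers 4 of 18. Of 6 erythroid markers, 2 reached 1 FPKM, and Hbb (a globin, named after its values were seen) was at 54.4, 357 and 348 in rat 1, rat 2 and rat 3.

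The design allows the question of which genes differ in level between the species after the same low-oxygen exposure. Among the 47 tested symbols whose rows have comparable spans, 19 were called higher in naked mole rat, 11 higher in rat and 17 in neither. Their median log2 difference was 0.50, against -0.20 over all 289 tested symbols. The scale was set over shared symbols of any span, so the balance of 19 to 11 and the folds below depend on it. Of the 19, GPX1 and ARRDC3 (named after its values were seen) have rat rows outside the assembled chromosomes, where 0 of 831 rows were above 0 in any rat; 17 of 45 remain without them. VNN3, a member of the vanin family of pantetheinases, was 11.3-fold higher in naked mole rat, at a scaled FPKM of 181 ± 8.07 against 15.1 ± 1.80 in rat (SD, n = 3 each; limma adjusted p = 1.02e-07). EEFSEC, the elongation factor for selenocysteine, was 8.33-fold higher, at 66.3 ± 14.6 against 7.01 ± 1.19 (limma adjusted p = 2.27e-06). MCM2, a replication licensing factor, was 3.50-fold higher at 9.11 ± 1.21 against 1.89 ± 0.288, and IDH3G, a subunit of the citric acid cycle's isocitrate dehydrogenase, 2.89-fold higher at 83.7 ± 8.81 against 28.2 ± 1.01. With quantile normalization the fold was 4.94 for IDH3G and 12.8 for EEFSEC. GPX1 stood at a scaled FPKM of 395 ± 96.2 in naked mole rat and was listed at 0 in each rat library.

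In the other direction, EDEM1, which targets misfolded glycoproteins for degradation, was 29.9-fold higher in rat, at 236 ± 79.8 against 6.75 ± 1.38 (SD, n = 3 each; limma adjusted p = 6.60e-07), or 19.7-fold with quantile normalization. MGLL, monoglyceride lipase, was 7.98-fold higher in rat, at 31.3 ± 5.93 against 3.24 ± 1.80 (limma adjusted p = 3.86e-05). RPL12, a ribosomal protein with near-identical copies, and TXNRD3, a thioredoxin reductase, were listed at 0 in the 3 naked mole rat libraries. In rat they were at FPKM values of 19.7, 16.2 and 18.0 and of 1.65, 2.11 and 1.58.

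**Figure D2:**
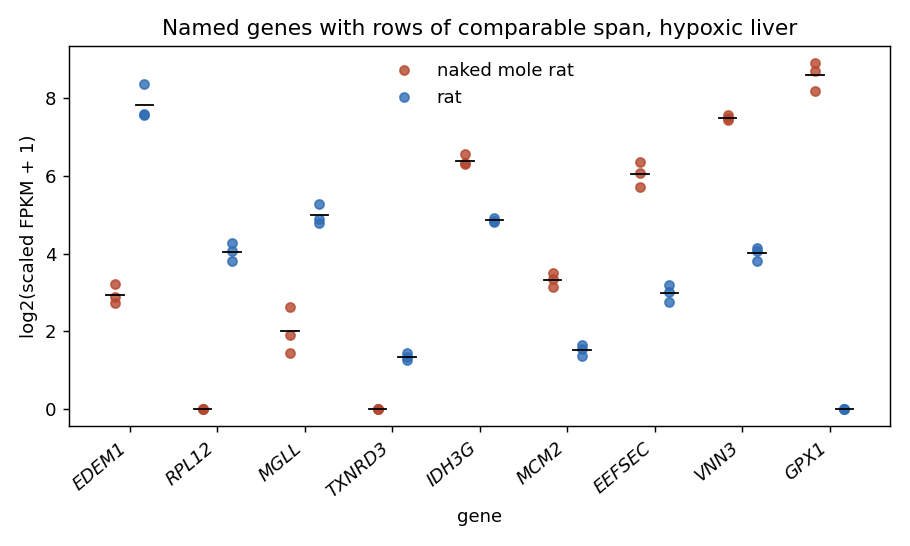
Named genes whose naked mole rat row spans 0.5 to 2 times the rat row, with log2(scaled FPKM + 1) on the y axis, 1 point per library (3 per species) and a black bar at the mean. In each of the 9 genes shown the libraries of the species do not overlap.

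Over all 289 tested symbols, 104 were called higher in naked mole rat and 109 higher in rat (limma; 258 at an unadjusted p under 0.05). Scaling each library to 1000000 over the shared symbols gave 143 and 95 calls and moved the median log2 difference from -0.20 to 0.82. That setting tested 298 symbols and kept the pseudocount of 1 on larger values, so the move is not of scale alone. FPKM as deposited gave 91 and 128 calls with a median of -0.62. Most of these symbols sit on rows of unlike extent: 179 long, 53 short and 10 with several rows, and species cannot be told apart from genome, annotation and alignment. On long rows 77 symbols were called higher in naked mole rat and 56 higher in rat; on short rows the numbers were 7 and 36. With comparable spans alone in the fit, on the same scale, 19 and 11 symbols were called, with a median of 0.50.

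The largest differences toward naked mole rat with a rat mean of at least 1 were UGT1A5 (785 ± 253 against 14.0 ± 2.59 scaled FPKM, SD, n = 3 each) and ERCC1 (339 ± 45.6 against 5.99 ± 0.504). Then came MIOX, of inositol breakdown, UGT1A6, MAPK12, TMED3, VNN3, UTP3, RIPK2, EEFSEC, AAAS and CYP1A2, from 19.1-fold for MIOX to 7.95-fold for CYP1A2. The MIOX fold was 12.3 without rat 2 and 29.2 with quantile normalization. UGT and CYP copies can split reads, and of these 12 symbols VNN3 and EEFSEC alone had rows of comparable span. In rat the UGT1A5 and UGT1A6 rows overlap, on chromosome 9 from 87052168 and from 87037153 to the same end at 87098362. Their differences may therefore not be separate results. The MIOX and MAPK12 rows overlap, on scaffold215 from 64568 to 315796 and from 297215 to 572162, so their values may not be separate. The same limit holds for ODF3 and COX8A, called in opposite directions, on scaffold477 from 10733 to 79080 and from 8941 to 70511. It also holds for FCGBP, on scaffold346 from 50898 to 1154995, a row within that of PSMC4, from 11865 to 1526216. DAPP1, CYP1A1, FCGBP and ODF3 stood between 43.8 and 263 scaled FPKM in naked mole rat and, with GPX1, had rat means under 1. A missing or shifted gene model in rat can give such low values. In naked mole rat the DAPP1 row spanned 818631 bp (50582 in rat), FCGBP 1104097 (37858), ODF3 68347 (3208) and CYP1A1 23866 (6031). Such long rows may also take in reads of neighbouring genes.

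Toward rat, the largest differences with a naked mole rat mean of at least 1 were APOH, a plasma glycoprotein, at 2983 ± 181 against 54.9 ± 11.8 (SD, n = 3 each), and PSMB5, a catalytic proteasome subunit, at 84.5 ± 7.22 against 1.08 ± 0.164. EDEM1, COX8A, HSPE1, DAD1, EIF5, HSPA8, CEBPG, VAMP7, MGLL and IVNS1ABP followed, from 29.9-fold for EDEM1 to 7.90-fold for IVNS1ABP. EDEM1 and MGLL alone had comparable spans. LDHA, TPT1 and GLUD1 were listed at 0 in the 3 naked mole rat libraries, against 1636, 1584 and 1480 FPKM for LDHA in rat. FTH1, the ferritin heavy chain, and RPS15A, a ribosomal protein with near-identical copies, were below 1 in naked mole rat. The naked mole rat row spanned 474 bp for LDHA (9471 in rat), 517 for TPT1 (2825) and 405 for FTH1 (2289). The GLUD1 row spanned 102726 bp (33537 in rat) and the RPS15A row 2510609 (5889). TPT1 and ribosomal proteins are used by nearly all cells, so a value of 0 here, for LDHA too, says only how the row is listed.

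**Figure D3:**
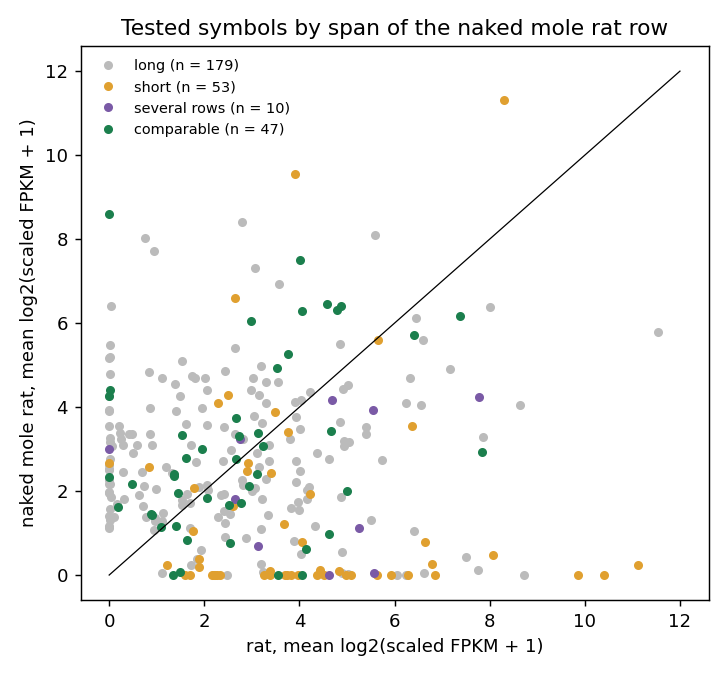
Each point is 1 of 289 tested symbols, with the mean log2(scaled FPKM + 1) over 3 libraries in rat on the x axis and in naked mole rat on the y axis, coloured by the span of the naked mole rat row relative to the rat row; the line marks equal levels. Short rows lie mainly along 0 in naked mole rat, and the 47 comparable rows have a Pearson's r of 0.29 against 0.030 for the 179 long rows.

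Across the 289 symbols the mean levels of the species had a Pearson's r of -0.011 and a Spearman's rho of -0.065, across genes, which are not independent replicates. For the 47 symbols of comparable span both were 0.29. Within a species, r between libraries over the same symbols was 0.977 to 0.991 in naked mole rat and 0.990 to 0.994 in rat. With no filter on low values, which keeps symbols low in both species, r between the species was 0.25.

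The gene lists had few members in the naked mole rat tables, and 4 had at least 3 tested. Of the chaperones, HSPE1, DNAJA1 and HSPA8 were each called higher in rat (3 of 3). HSPE1 spanned 3263939 bp in naked mole rat and 3089 bp in rat, DNAJA1 2627575 and 10912 bp, and HSPA8 had several rows. Of the proteasome subunits, PSMB5 and PSMA4 were called higher in rat and PSMC4 in naked mole rat. No tested chaperone or proteasome subunit had rows of comparable span, so these calls cannot be told apart from row extent. Of the citric acid cycle genes, IDH1 and SUCLA2 were called higher in rat, both listed at 0 in naked mole rat, and IDH3G higher in naked mole rat. Among these, IDH3G alone had rows of comparable span. Of 6 tested xenobiotic genes, 3 were called higher in naked mole rat, among them CYP1A1 and UGT1A6, whose copies can split reads, and 3 in neither. Only UGT1A1, called in neither, had rows of comparable span, and in rat its row lies within that of UGT1A6. The counts adjusted over the list alone were equal to these in all 4 lists. No list was called by camera (0 in each direction, 1 list at an unadjusted p under 0.05). The chaperones had an adjusted p of 0.142, with a median log2 difference of -4.56, and an adjusted p = 0.466 with an estimated correlation; the other 3 lists had an adjusted p of 0.470, and adjusted p = 0.600 with an estimated correlation. fry, which asks whether a list's members move one way and not whether they differ from other genes, called 1 list higher in naked mole rat and 3 higher in rat.

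Lists with 1 or 2 tested members contributed single genes. The respiratory chain genes COX7A2 and COX8A, the ribosomal proteins RPL12 and RPS24, ATG3 of autophagy, CFP (properdin) of the complement system, the cyclophilin PPIA, TXNIP and SEPHS2 were called higher in rat. Of these, COX8A, CFP and SEPHS2 had a mean above 1 in naked mole rat, at 15.7 ± 3.62, 6.58 ± 0.979 and 10.7 ± 1.31 scaled FPKM (SD, n = 3). RPL12 alone among these 9 had a comparable span, with rows of 450 bp in naked mole rat and 498 bp in rat. The ratio of spans cannot tell whether such rows are short copies in both species.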

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

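The tests in this part were chosen after the results they bear on had been seen; the counts over other splits of the libraries were planned, with what they would show written down only afterwards.

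Signal also appeared in naked mole rat rows that entered no comparison, because they carry no symbol or one with no match in the rat tables; such rows held 63.0% of the table's FPKM total. The row without a symbol on scaffold130497, 660 bp long, had a mean of 6550 FPKM (5380 to 8586 over 3 libraries). Those on scaffold35662 (262 to 427) and scaffold48809 (27689 to 41759) had means of 215 and 189 FPKM. CYP27C1 on scaffold175241 had a mean of 1951 FPKM, CYP2B6 on scaffold76895 1405 and CYP3A5 on scaffold175419 514, with copies that can split reads.

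The first pattern is the 77 symbols called higher in naked mole rat on rows longer than the rat gene, for which a candidate explanation is that such a row takes in reads of neighbouring genes. For 71 of them with rat neighbours within the naked mole rat span, grouped into 59 regions because some share a neighbourhood, the naked mole rat level followed the mean rat FPKM of those neighbours, with a partial Spearman's rho of 0.36 given the gene's own rat level (two-sided permutation test over regions, p = 0.00471). Over the 71 symbols the partial rho was 0.32 and the plain rho 0.36; the adjustment and then the regions were added once the plain value was known. The level followed the gene's own rat level more closely (rho 0.60 over the 71 symbols, which the call itself favours), and 43.0% of long rows against 40.4% of rows of comparable span were called higher in naked mole rat (Fisher's exact test, two-sided, p = 0.869), or 42.0% against 37.8% (p = 0.735) without rat rows outside the assembled chromosomes. A difference between the species in the genes themselves cannot be told apart from this, since species and annotation coincide.

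The second pattern is the 63 symbols called higher in rat with a naked mole rat mean under 1. A short copy carrying the symbol in place of the full gene is a candidate explanation: of the 60 with 1 row per species, 55.0% had a row under 0.5 times the rat span, against 9.13% of the other tested symbols (Fisher's exact test, two-sided, p = 2.10e-13). Too few naked mole rat reads stays open for the set: the rat levels had a lower quartile of 4.46 scaled FPKM, within 10 times of 0.50, the median of the lowest values above 0 on naked mole rat rows under 1000 bp, although 45 of the 63 lay above 10 times that value, with FTH1 at 2207 and LDHA at 1366. The reads may have been too few to detect part of the 63, and this cannot be told apart from a lower level. A lower level in naked mole rat liver stays open and was not tested.

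The third pattern is the 20 symbols called higher in naked mole rat and listed at 0 in the 3 rats. For ARRDC3, GAA, GPX1, PTGFR and STEAP3 the rat row lies outside the assembled chromosomes, where 0 of 831 rows were above 0 in any rat, so that reads there may not have been counted. By the placement of their rows alone, and not by a test, this explanation cannot apply to the other 15, on assembled chromosomes. Most of the 15 sit on long rows, as in the first pattern, and CKMT2 alone has a row of comparable span. The genes named for this pattern, apart from GPX1, were named after their values were seen, and a difference between the species was not tested apart from annotation.

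For the counts of calls, 1 of the 10 splits of the 6 libraries, the real one, gave 104 symbols higher in naked mole rat and 109 higher in rat, and the highest count in any other split was 0. With 10 splits the share cannot fall under 0.05.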

How the results depend on the processing

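The restriction to comparable spans, the matches through synonyms and the omission of rat rows outside the assembled chromosomes were chosen after seeing the data; the other settings were fixed before. The count of symbols called higher in naked mole rat (104) became 45 with at least 1 FPKM in all 6 libraries, 62 with a log2 difference of at least 2 and 19 with comparable spans alone; the count higher in rat (109) became 42 and 11 under the first and the last. These settings test fewer symbols or ask for a larger difference. The other settings stayed within 1.5 times, and leaving out 1 library gave 98 to 108 and 111 to 118 calls. The sum to 1000000 gave 143 and 95. Lists called by fry numbered 1 higher in naked mole rat and 3 higher in rat, against 0 and 0 with camera, since fry does not compare a list with other genes; leaving out 1 library gave 0 in both directions. The correlation between the species moved from -0.011 to -0.13 with a pseudocount of 0.1 and to 0.25 with no filter. The filter leaves out symbols low in both species, so r over the tested symbols is in part a product of it. The cause of the move with the pseudocount was not tested. Leaving out 1 library gave -0.015 to -0.0060. Over the tested symbols, the median SD between naked mole rat libraries was 0.153 over 3 libraries and 0.0914 to 0.145 over 2, lowest without naked mole rat 3. That between rat libraries was 0.110 over 3 and 0.0853 to 0.0964 over 2. The median of an SD over 2 libraries tends to be lower than over 3, so the lower values need not come from the library left out. Of 571 recomputed differences of the 51 tested genes that the naming rule takes, 565 kept their direction and side of the threshold. Of the rest, 6 lost the call and 0 changed sign. All 51 were called in the main fit, and the rule picks most genes for being called, so kept calls were favoured. The settings with no filter, with the replicate block and with comparable spans alone left the log2 differences of these genes unchanged. No setting changed the extent of a row, so the count does not bear on rows of unlike extent. The fold moved by over 1.5 times under FPKM as deposited or quantile normalization in 16 of the 51. Replicate numbers did not pair the libraries: the deviations of libraries with the same number correlated at -0.050, -0.087 and -0.051, and the replicate block gave 104 and 109 calls, changing neither count of calls. Depth cannot be recovered from these values, so low symbols cannot be separated into absent and undetected.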

Other observations

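The rat tables alone show which liver programmes differed among the 3 libraries under the same exposure; these genes, other than Ttr, were named after their values were seen. Of 46 lists compared with 10000 random lists matched on mean expression, the acute-phase, cholesterol synthesis, fatty acid synthesis, hypoxia-inducible factor target and immediate early lists had a median SD above that of every random list (percentile 100). In all, 14 of the 46 lists lay above percentile 99. Among them were the interferon and antigen presentation list (percentile 99.99) and the markers of stellate cells or fibroblasts (99.99), macrophages or Kupffer cells (99.96), neutrophils (99.92, 4 members) and T or NK cells (99.51, 3 members). Markers of cholangiocytes (98.95, 3 members), hepatocytes (83.7), sinusoidal endothelium (31.5) and proliferation (27.2, 4 members) were not among them. Acute-phase genes were lowest in rat 2 for 15 of 19 members: the fibrinogen chain Fgb was at 8594, 2256 and 8667 FPKM in rat 1, rat 2 and rat 3, the haem-binding protein hemopexin (Hpx) at 5657, 2531 and 6958, and Lbp, which binds bacterial lipopolysaccharide, at 172, 62.7 and 156. Not all members did so, with Ttr at 9869, 12914 and 10322 and Apcs at 271, 272 and 282.

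Cholesterol synthesis genes took another order, lowest in rat 1 for 20 of 22 members and highest in rat 3 for 19. Fdps, of isoprenoid synthesis, was at 45.0, 50.6 and 95.5 FPKM in rat 1, rat 2 and rat 3. Insig1, a sterol sensor, was also highest in rat 3 but slightly lower in rat 2 than in rat 1, at 45.8, 44.8 and 108. Of the hypoxia-inducible factor targets, 15 of 27 were lowest in rat 3 and 13 highest in rat 1; Bnip3, of mitochondrial turnover, was at 64.6, 68.8 and 23.4 and Ankrd37 at 9.14, 1.68 and 5.59. The globin Hba-a2, whose near-identical copies can split reads, was at 336, 1974 and 2282, low in rat 1 as was Hbb. In contrast, the respiratory chain list of complexes II to V (percentile 0.010), the ribosomal proteins (0.24) and the chaperones (0.37) varied less than nearly all random lists. With 3 libraries and no further labels, no explanation was tested.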
